A study of Homo sapiens with 8 samples.

How the data were processed

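Total RNA from 8 cultures of human NK cells was hybridized to Illumina HumanHT-12 v4 BeadChips, 1 array per culture. The cultures came from 2 donors, each with and without immobilized IgG1 (wells coated at 50 µg/ml) for 4 h and for 24 h, per the labels' protocols. The deposited table holds log2 intensity values made by the authors for 32639 probes on the 8 arrays. The submitters' processing notes name limma, with the version not given in the sources used here. From the values, the minimum was 6.07 and the maximum 14.3 on every array and the quartiles matched between arrays, as quantile normalization leaves them. The background correction, any offset before the logarithm and any probe filter are not given in the sources used here, and detection calls were not used here. A common distribution sets a limit: a shift shared by most genes on an array has been removed, and any background left in the signal would compress the fold changes of dim probes.

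Probes were named through the platform annotation. Of the probes in the table, 16953 had 1 gene symbol, 8 had several and 15678 had no name here, and 90.0% of the named probes carried symbols that begin with A to M. Members of the gene lists later in the alphabet are therefore mostly not analysed here, among them TNF, CSF2, XCL1, TNFRSF9, PRF1, NR4A3 and MYC, which the rule for named genes would have included. Human gene names were taken from the annotation and a RefSeq table for assembly GRCh38.p14, used for names and not for positions. No genome build is named in the sources used here, so no coordinates are given. The 48 probes of XIST and Y-linked genes were left out because they can tell a donor's sex.

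A probe was tested if it lay above its array's 50th percentile on at least 2 of the 8 arrays, which left 20783 probes. Each gene was represented by its probe with the highest mean over the 8 arrays, giving 8085 genes out of 11466 with a named probe, and 2078 of them had more than 1 tested probe. A gene is called dim where it lay under the 50th percentile on both arrays of a group. Among the genes named, CCL1 was dim in every group except IgG1 at 24 h, CD3E and EBI3 without IgG1 at 4 h, ICA1 with IgG1 at 4 h, and FOSB and MIR155HG without IgG1 at 24 h.

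The deposited values were fitted without further normalization in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, no trend, not robust), with 1 mean per group over all 8 arrays, so that the 4 groups shared 1 estimate of the spread with 4 residual degrees of freedom. The 5 contrasts were IgG1 against no IgG1 at 4 h and at 24 h, the difference between these effects, and 24 h against 4 h without and with IgG1. Adjusted p-values use the Benjamini-Hochberg method over all genes of 1 contrast, and a gene is called at an adjusted p under 0.05. With 2 donors, p-values measure the spread between these donors and the cultures made from them. Because replicate 1 and replicate 2 are the same donors in every group, per the labels, the numbers pair the arrays, and the fit with the donor as a block was the first alternative. Deviations of the same donor from the group means correlated with r between 0.0294 and 0.352 over the 6 pairs of groups. Results are given with the block where it changes a call or moves a count by over 1.5 times.

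Gene lists (21 programs and 7 sets of markers of other blood cells) were fixed before the data were examined and tested with limma's camera with a preset inter-gene correlation of 0.01 on lists with at least 3 tested members, with Benjamini-Hochberg adjustment over the lists of 1 kind in 1 comparison. With the correlation estimated from the data, 0 lists were called in each of the 5 comparisons. The lists were written from general knowledge and not from these arrays, and some genes stand in more than 1 list.

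Named genes followed a rule fixed before the data were examined. For each IgG1 comparison these were the 10 highest and 10 lowest called genes that moved the same way in both donors, or, with no call, the 5 highest and 5 lowest moderated statistics. Up to 4 members of each list and a fixed set of NK activation genes were added. Symbols that are only a locus or clone identifier were counted and not named. For the other comparisons the 5 highest and 5 lowest called genes were named. The genes named for the difference between times, and those named for the 2 time comparisons beyond these 5, were chosen after their values were seen.

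The fit was tested on simulated data for the 24 h comparison, with 8085 genes, spreads drawn from limma's fitted prior and 200 changed genes in each of 20 runs. Of the changed genes, 10.8% were called at a log2 size of 0.5, 74.3% at 1, 93.6% at 1.5 and 97.3% at 2, all with the right sign, and 4.43% of the called genes were false. A list of 20 genes shifted by 0.3 was called in all 20 runs, and 0 of 380 unshifted lists were called. The simulated genes varied independently of each other. The runs therefore cannot show how often the list test calls falsely where the genes of a list are correlated.

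Alternatives were the donor as a block or as a random effect, no filter, a filter at the 70th percentile, quantile normalization of the deposited values, centring each array on its median, a trended and robust variance, the mean of a gene's probes, testing every probe, a minimum absolute log2 fold change of 1, only the 4 arrays of a time for the IgG1 comparisons, and leaving out each array. Figures were drawn with matplotlib 3.10.9.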

Results

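Natural killer (NK) cells are blood lymphocytes that kill antibody-coated cells after their Fc receptor CD16, encoded by FCGR3A, binds IgG. Gene expression was measured in human NK cells purified from blood by removing other cell types. The cells were cultured for 4 h or 24 h in wells coated with human IgG1 at 50 µg/ml or in wells without it. Cells of 2 donors were used in each of the 4 groups, which gave 8 Illumina HumanHT-12 BeadChip arrays. Replicate 1 and replicate 2 name the same donor in every group. The deposited values are log2 intensities on a common distribution, with a median of 6.53 on each array. Across the 8085 genes tested, the donors of a group correlated with r between 0.955 and 0.972, over genes, which are not independent replicates. With 2 arrays per group, the number of arrays limits the precision, and the median standard error (SE) of a log2 fold change between 2 groups was 0.14. Values below are log2 fold changes ± SE from the limma fit over all 8 arrays, with 2 donors per group, and all p-values are two-sided. Counts of list members cover only the tested members, since most genes with symbols after M had no named probe.

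The first comparison asked which transcripts NK cells changed within 4 h on immobilized IgG1. As a group, the cytokine and chemokine genes of activated NK cells rose. Of 17 members, 15 were higher with IgG1, with a median of 0.20 (adjusted p = 0.0011 with limma's camera, adjusted p = 0.261 with an estimated correlation). IFNG, which encodes interferon-gamma, stood at 1.81 ± 0.56 and was higher in both donors (2.59 and 1.02). It stood at 0.84 without no IgG1 4 h replicate 1 and at 2.77 without no IgG1 4 h replicate 2. The chemokine genes CCL3L1, CCL4L1, CCL3 and CCL4 stood at 1.58 ± 0.51, 1.44 ± 0.30, 1.39 ± 0.30 and 0.99 ± 0.33. Without the same 2 arrays in turn CCL3L1 stood at 0.74 and 2.42, and CCL4 stood at 0.58 without no IgG1 4 h replicate 1 and at 0.65 without IgG1 4 h replicate 2. CCL3 and CCL3L1, like CCL4 and CCL4L1, are near-identical copies, so their separate values are uncertain. The list test and the counts of cytokine members take them as separate genes in every comparison. The same signal can therefore be counted more than once there.

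Immediate early and calcium-responsive transcription factor genes, which receptor signalling switches on early, also rose as a group at 4 h. Of 23 members, 19 were higher, with a median of 0.51 (adjusted p = 2.04e-08, adjusted p = 0.0990 with an estimated correlation). EGR1 stood at 1.38 ± 0.55 (2.07 and 0.70 in the donors), IRF4 at 1.11 ± 0.43, FOSB at 0.98 ± 0.16 and DUSP5, a phosphatase that acts on ERK, at 0.97 ± 0.19. EGR1 stood at 0.42 without no IgG1 4 h replicate 1 and at 2.34 without no IgG1 4 h replicate 2, and IRF4 at 0.65 without IgG1 4 h replicate 1. Adhesion and migration receptors fell as a group, with 14 of 19 members lower and a median of -0.14 (adjusted p = 0.033, adjusted p = 0.261 with an estimated correlation). The fractalkine receptor gene CX3CR1 stood at -1.40 ± 0.36, ITGAM at -0.56 ± 0.16, ITGAL at -0.52 ± 0.11 and ITGAE at -0.51 ± 0.19 (-0.79 and -0.23 without IgG1 4 h replicate 1 or 2). With all genes put into 10 groups by brightness, the median at 4 h was -0.11 in the second brightest. The adhesion call ended without no IgG1 4 h replicate 1 (adjusted p = 0.294) or IgG1 4 h replicate 2 (0.118). The number of lists called at 4 h, 3 with all arrays, was 6 without no IgG1 4 h replicate 2, 5 without IgG1 4 h replicate 2 and 2 without no IgG1 4 h replicate 1.

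No single gene passed the threshold at 4 h in limma with Benjamini-Hochberg adjustment, where the smallest adjusted p was 0.180. An unadjusted p under 0.05 was found for 967 genes (381 higher and 586 lower), against 404 by chance. Adjusted over the list alone, 2 cytokine genes (6 with the donor block) and 8 immediate early genes passed, all higher, and 1 adhesion gene (3 with the block) passed, lower, against 0 of each over all genes tested. The genes with the highest moderated statistics, none past the threshold, included the checkpoint gene VSIR at 1.41 ± 0.16 and MIR155HG, the host gene of microRNA-155, at 1.18 ± 0.17. MCEMP1 stood at 0.70 ± 0.11, GADD45A at 0.80 ± 0.13 and IHH at 1.15 ± 0.19. At the other end stood GLRX at -1.08 ± 0.12, CD8A at -0.97 ± 0.12, ARHGAP30 at -1.09 ± 0.15, ATP6V1A at -0.91 ± 0.13 and the transcription factor FLI1 at -0.78 ± 0.11. With a gene's probes averaged GADD45A stood at 0.51 and ARHGAP30 at -0.62.

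Receptor and effector genes at 4 h also missed the threshold one by one. The receptor gene CD160 stood at 1.44 ± 0.24, CRTAM, a surface protein of activated cytotoxic cells, at 1.34 ± 0.41 and the inhibitory receptor CD300A at -1.12 ± 0.28 (-0.65 without IgG1 4 h replicate 2). CD69 stood at 0.52 ± 0.15, CD38 at -0.55 ± 0.12 and IL2RA, a chain of the IL-2 receptor, at 0.42 ± 0.28 (-0.0017 and 0.84 without IgG1 4 h replicate 1 or 2, 0.26 with its probes averaged). In the cytotoxic list FASLG stood at 0.63 ± 0.18, GZMB at 0.48 ± 0.18, FGFBP2 at -0.79 ± 0.32 and GZMH at -0.65 ± 0.20, and the list was not called (adjusted p = 0.530). FGFBP2 stood at -0.43 without IgG1 4 h replicate 1, and GZMB at 0.29 without no IgG1 4 h replicate 1 and at 0.31 without IgG1 4 h replicate 2. In the Fc receptor and ITAM signalling list FCGR3A stood at -0.67 ± 0.23, LAT at -0.68 ± 0.19, INPP5D at -0.53 ± 0.11 and LCK at -0.50 ± 0.10. With a gene's probes averaged FCGR3A stood at -0.24 and LCK at -0.20. That list missed the threshold without the donor block (adjusted p = 0.0501) and passed with it (adjusted p = 0.0451). It was not called with the other setting for the correlation (adjusted p = 0.348 with an estimated correlation).

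The second comparison asked the same question after 24 h. Here 26 genes were called, 9 higher and 17 lower with IgG1, and each moved the same way in both donors. The cytotoxic granule genes that were tested fell: all 13 tested of the 20 genes on the list had lower values, with a median of -0.42 (adjusted p = 2.30e-07, adjusted p = 0.127 with an estimated correlation). GZMA, which encodes granzyme A, stood at -2.38 ± 0.22 (adjusted p = 0.0203) and GZMH, granzyme H, at -1.52 ± 0.20 (adjusted p = 0.0439). These 2 members were called over all genes and 5 adjusted over the list alone (8 with the donor block), all lower. FGFBP2 at -1.41 ± 0.32, GZMK at -1.17 ± 0.56 (-0.74 without no IgG1 24 h replicate 1) and GZMB, granzyme B, at -0.65 ± 0.18 did not pass the threshold.

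**Figure D1:**
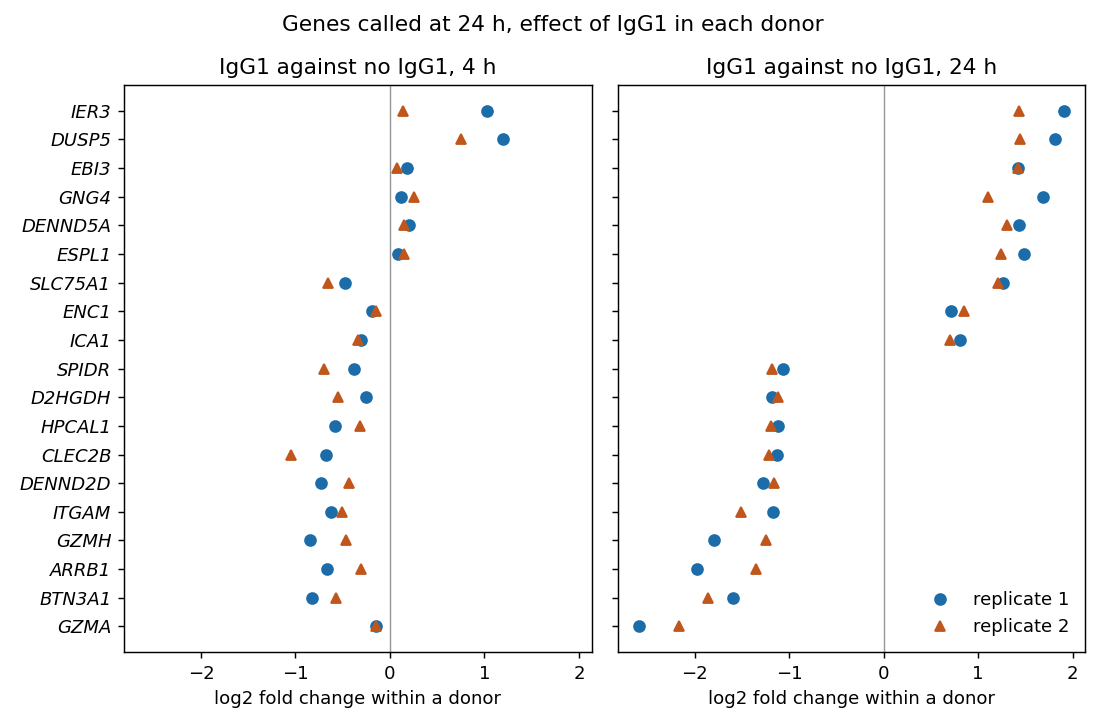
Log2 fold change with IgG1 within each donor (horizontal axes) at 4 h on the left and at 24 h on the right, for 19 of the genes called at 24 h (vertical axis), with circles for replicate 1 and triangles for replicate 2. At 24 h both donors lie on the same side of 0 for every gene shown, which was a condition for a gene to be shown. GZMA, at -2.38 on average, lies farthest from 0.

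The Fc receptor and ITAM signalling list fell at 24 h, with 10 of 14 members lower and a median of -0.24 (adjusted p = 0.00558, adjusted p = 0.189 with an estimated correlation). LCK, a kinase that acts just below immune receptors, was its 1 member called over all genes, at -0.73 ± 0.10 (adjusted p = 0.0477). That value is of its brightest probe: the 3 further probes of LCK gave -0.74, 0.16 and -0.02, and with the probes averaged it stood at -0.33 and was not called (adjusted p = 0.298). With the donor block 4 members were called, all lower. Adjusted over the list alone, 5 members passed lower and 1 higher (0 higher with the block). FCGR3A itself stood at -1.52 ± 0.23, with an adjusted p of 0.0592 without and 0.0281 with the donor block, and at -0.80 with its probes averaged (adjusted p = 0.145). FCER1G, its signalling partner, stood at -1.36 ± 0.22, with 0.0789 and 0.0281, and INPP5D, an inhibitory phosphatase, at -0.78 ± 0.11, with 0.0552 and 0.0498. The list call ended without IgG1 24 h replicate 1 (adjusted p = 0.0532).

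The list of natural cytotoxicity and other activating receptors fell at 24 h, with 11 of 17 members lower and a median of -0.19 (adjusted p = 0.0393, adjusted p = 0.234 with an estimated correlation). It is called the activating receptor list below, but it also held inhibitory KIR genes such as KIR3DL1 and cytokine receptor genes such as IL12RB1. The fall of this list is therefore not a fall of activating receptors as a class. CD244, which binds CD48, was its 1 member called over all genes, at -1.08 ± 0.14 (adjusted p = 0.0388), with 2 called with the donor block, and 3 passed lower and 1 higher adjusted over the list alone. KLRF1 stood at -1.47 ± 0.24 (adjusted p = 0.0745) and the interleukin-12 receptor gene IL12RB2 at 0.96 ± 0.24 (0.58 without no IgG1 24 h replicate 1). KLRC3 stood at -0.98 ± 0.26, with an adjusted p of 0.243 without and 0.0423 with the donor block, and at -0.40 with its probes averaged. The list was no longer called without no IgG1 24 h replicate 1 (adjusted p = 0.109), no IgG1 24 h replicate 2 (0.0582) or IgG1 24 h replicate 2 (0.381).

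The adhesion and migration receptors fell at 24 h too, with 14 of 19 members lower and a median of -0.20 (adjusted p = 0.0143, adjusted p = 0.189 with an estimated correlation). ITGAM, the CD11b integrin chain, was the 1 member called over all genes, at -1.34 ± 0.16 (adjusted p = 0.0388), against 3 lower and 1 higher adjusted over the list alone. With the donor block 3 were called over all genes, all lower, and 2 passed higher adjusted over the list alone. S1PR1, a receptor for lymphocyte exit from tissue, stood at -1.91 ± 0.27, with an adjusted p of 0.0534 without and 0.0074 with the donor block. CX3CR1 stood at -1.44 ± 0.36, with 0.217 and 0.0281, and at -0.95 without IgG1 24 h replicate 1, and the lymph node homing receptor CCR7 at 0.88 ± 0.28. KLF2, a transcription factor that drives S1PR1, stood at -2.35 ± 0.37, with an adjusted p of 0.0718, of 0.0318 with the donor block and of 0.0283 without either IgG1 4 h array. The adhesion list was not called without no IgG1 24 h replicate 1 (adjusted p = 0.0925).

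The type I interferon-stimulated genes fell as a list at 24 h, with 19 of 23 members lower and a median of -0.18 (adjusted p = 0.00162, adjusted p = 0.371 with an estimated correlation). Of its members 0 were called over all genes in limma (1 with the donor block) and 2 adjusted over the list alone, both lower. IFITM2 stood at -1.10 ± 0.21, with an adjusted p of 0.114 without and 0.0379 with the donor block, IFITM3 at -0.76 ± 0.17 and IFITM1 at -0.69 ± 0.21 (-0.43 without no IgG1 24 h replicate 1).

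The immediate early list rose at 24 h, with 18 of 23 members higher and a median of 0.22 (adjusted p = 2.86e-06, adjusted p = 0.127 with an estimated correlation). Its 2 called members were IER3 at 1.67 ± 0.23 (adjusted p = 0.0477) and DUSP5 at 1.63 ± 0.19 (adjusted p = 0.0374), against 4 with the donor block, and 7 passed adjusted over the list alone, all higher. JUN at 1.97 ± 0.59 (1.03 without no IgG1 24 h replicate 1) and IRF4 at 1.31 ± 0.43 (0.74 without IgG1 24 h replicate 1) did not pass. The activation surface markers rose as a list, with 8 of 10 members higher and a median of 0.28 (adjusted p = 0.00202, adjusted p = 0.309 with an estimated correlation). Of these, 0 were called over all genes in limma and 2 adjusted over the list alone (4 with the donor block), all higher. CRTAM stood at 1.85 ± 0.41 (1.18 without no IgG1 24 h replicate 1), IL2RA at 0.88 ± 0.28, CD82 at 0.70 ± 0.13, CD69 at 0.42 ± 0.15 (0.26 without IgG1 24 h replicate 2) and IL2RB at -0.60 ± 0.30.

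**Figure D2:**
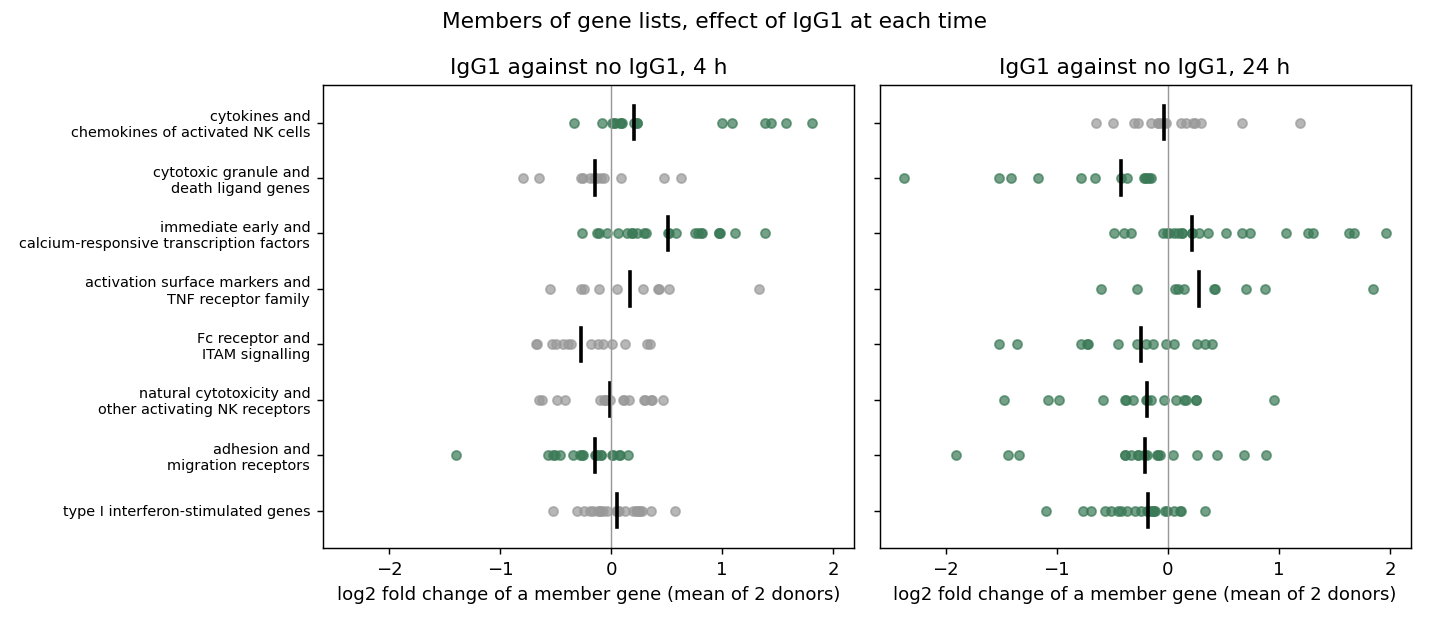
Log2 fold change with IgG1 (horizontal axes, mean of 2 donors) of each tested member of the 8 gene lists called at 4 h or 24 h (vertical axis), with 1 point per gene, a black bar at the list's median, green for a list called at that time with the preset correlation and grey for one that was not. The cytokine list has its median at 0.20 at 4 h and -0.03 at 24 h, and the cytotoxic list at -0.14 and -0.42.

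The other genes called higher at 24 h were EBI3, a subunit of IL-27 and IL-35, at 1.42 ± 0.12 (adjusted p = 0.0203), GNG4 at 1.39 ± 0.20, DENND5A at 1.37 ± 0.15 and ESPL1, which encodes separase, at 1.36 ± 0.13. SLC75A1 at 1.24 ± 0.17, ENC1 at 0.78 ± 0.11 and ICA1 at 0.76 ± 0.10 completed them. Those called lower included BTN3A1, a butyrophilin, at -1.73 ± 0.15 (adjusted p = 0.0203), ARRB1, beta-arrestin 1, at -1.66 ± 0.18 and DENND2D at -1.22 ± 0.13. CLEC2B, a ligand of the receptor that KLRF1 encodes, stood at -1.17 ± 0.13, HPCAL1 at -1.15 ± 0.14, D2HGDH at -1.15 ± 0.15 and SPIDR at -1.12 ± 0.14. A dimmer probe of HPCAL1 gave -0.01 and of D2HGDH -0.08, and the 3 further probes of ICA1 lay between -0.10 and 0.53. When a gene's probes were averaged, DENND5A (0.87, adjusted p = 0.137), ICA1 (0.30, 0.303), ARRB1 (-1.01, 0.198), HPCAL1 (-0.58, 0.171) and D2HGDH (-0.62, 0.0691) were no longer called, nor was LCK. The same held for IER3, GNG4, SLC75A1, ENC1 and GZMH, whose fold changes stayed as they were and whose adjusted p then lay between 0.0529 and 0.0597.

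Cytokine genes were not called as a list at 24 h (adjusted p = 0.980), and adjusted over the list alone 1 member passed higher and 1 lower. CCL1 stood at 1.19 ± 0.20 (adjusted p = 0.0777), IFNG at 0.67 ± 0.56, CCL4 at 0.22 ± 0.33, CCL3 at 0.12 ± 0.30 and CCL5 at -0.64 ± 0.14. IFNG stood at 0.41 without no IgG1 24 h replicate 1 and at 0.35 without IgG1 24 h replicate 2, CCL4 at 0.12 without no IgG1 24 h replicate 1 and at 0.48 and -0.03 without IgG1 24 h replicate 1 or 2, and CCL3 at 0.28 and -0.03 without no IgG1 24 h replicate 1 or 2. The checkpoint gene HAVCR2 stood at 0.98 ± 0.16 (adjusted p = 0.0745). CD300A stood at -1.47 ± 0.28, with an adjusted p of 0.125, and of 0.0283 without either IgG1 4 h array. Inhibitory receptors as a list were not called (adjusted p = 0.518 at 4 h and 0.980 at 24 h).

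The count of 26 rested on every array: it was 0 without no IgG1 4 h replicate 1 or 2, IgG1 24 h replicate 1 or 2, or no IgG1 24 h replicate 1, 1 without no IgG1 24 h replicate 2, and 14 without IgG1 4 h replicate 1 or 2. It was 53 with the donor block (13 higher and 40 lower, all 26 among them), 12 with a gene's probes averaged, 8 when every probe was tested and 0 with the 4 arrays of 24 h alone, where limma gave no adjusted p under 0.05.

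The third comparison tested whether the effect of IgG1 differed between 24 h and 4 h. Cytokine and cytotoxic genes had lower effects at 24 h than at 4 h, as lists. The median difference was -0.31 for the cytokine list, with 15 of 17 members lower (adjusted p = 0.00353, adjusted p = 0.294 with an estimated correlation). It was -0.52 for the cytotoxic list, with 11 of 13 lower (adjusted p = 0.000228, adjusted p = 0.294 with an estimated correlation). Type I interferon-stimulated genes had a median difference of -0.37 (adjusted p = 0.00098, adjusted p = 0.713 with an estimated correlation) and the activating receptor list of -0.20 (adjusted p = 0.0323, adjusted p = 0.294 with an estimated correlation). Oxidative phosphorylation genes, which encode the respiratory chain, had a median difference of 0.23 (adjusted p = 0.0402, adjusted p = 0.713 with an estimated correlation). All 11 tested of the 32 genes on that list were lower with IgG1 at 4 h, with a median of -0.17. At 24 h its largest effects were 0.23 for COX5A and -0.13 for ATP5F1C. The difference thus reflects lower values at 4 h more than a rise at 24 h. Adjusted over the list alone, 3 cytotoxic genes (5 with the donor block) passed, all lower, and 0 genes of the other 4 lists in limma. With the block 1 cytokine gene passed higher and 1 lower.

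No single gene passed the test of this difference in limma, where 489 genes had an unadjusted p under 0.05 against 404 by chance and the smallest adjusted p was 0.287. The difference was -2.23 ± 0.31 for GZMA, -1.59 ± 0.42 for CCL4L1, -1.26 ± 0.43 for CCL3 and -1.14 ± 0.80 for IFNG (-0.17 and -2.10 without no IgG1 4 h replicate 1 or 2), so a change of these single genes' effects with time was not shown. The 5 list calls became 2 without no IgG1 4 h replicate 1 and 3 without no IgG1 24 h replicate 1, no IgG1 24 h replicate 2 or IgG1 24 h replicate 2. Among the lists, the oxidative phosphorylation call ended without any 1 of the 6 arrays other than IgG1 4 h replicate 1 and IgG1 24 h replicate 1 (adjusted p between 0.0610 and 0.813). The call of the activating receptor list ended without replicate 1 of either 4 h group, either no IgG1 24 h array or IgG1 24 h replicate 2 (0.0739 to 0.116), and that of the interferon-stimulated genes without no IgG1 4 h replicate 1 (0.127) or IgG1 4 h replicate 1 (0.0673).

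**Figure D3:**
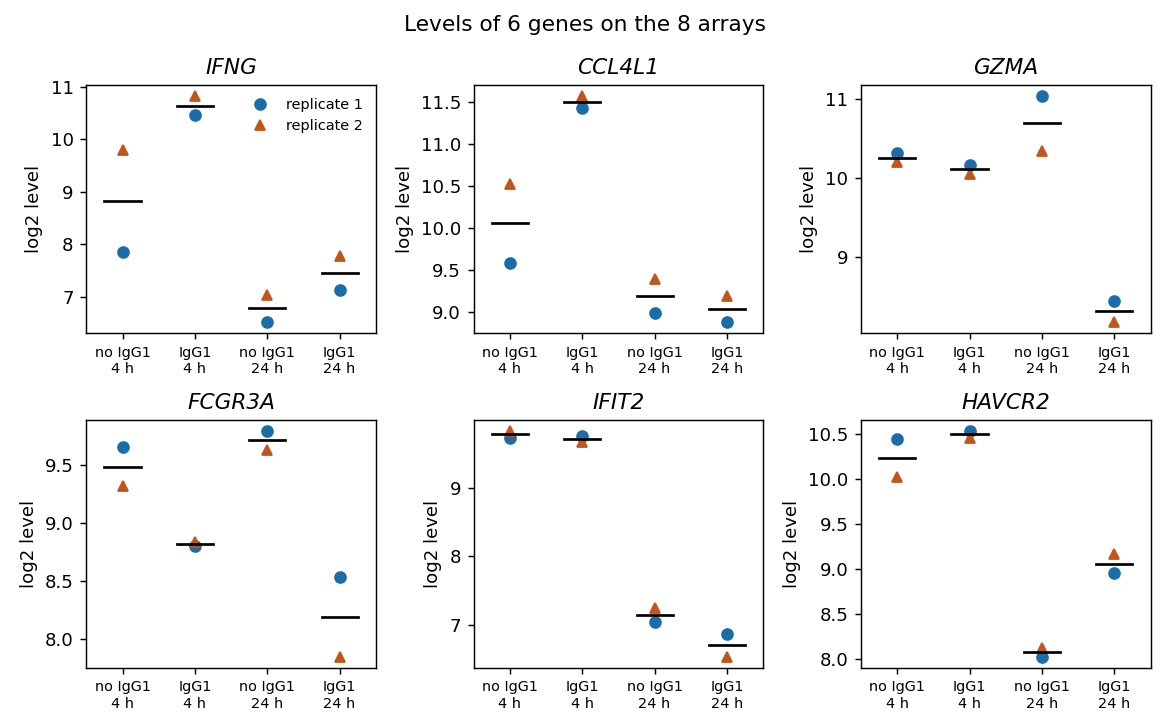
Log2 level (vertical axes, each with its own range) of 6 genes on the 8 arrays by group (horizontal axes), with circles for replicate 1, triangles for replicate 2 and a line at the mean of the 2 donors. IFNG lies between 10.5 and 10.8 with IgG1 at 4 h and between 7.14 and 7.77 with IgG1 at 24 h, and GZMA lies at 8.45 and 8.18 with IgG1 at 24 h.

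Expression also changed with time in culture. Without IgG1, 9 genes were lower at 24 h than at 4 h, each in both donors, and 0 were higher in limma. Of these, 6 were type I interferon-stimulated genes: IFIT1 at -2.96 ± 0.22 (adjusted p = 0.00506), IFIT3 at -2.82 ± 0.32, IFIT2 at -2.63 ± 0.14, HERC5 at -2.02 ± 0.17, ISG15 and ISG20. With a gene's probes averaged IFIT1 stood at -1.54 and IFIT3 at -1.48, and both were called. The checkpoint gene HAVCR2, which encodes TIM-3, stood at -2.16 ± 0.16 (adjusted p = 0.00506), and CD69, an early activation marker, and CRIP1 completed the set. All 23 interferon-stimulated genes tested had lower values at 24 h, with a median of -0.93 (adjusted p = 8.31e-24, adjusted p = 0.130 with an estimated correlation), and 15 passed adjusted over the list alone.

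Without IgG1, 5 other lists fell between 4 h and 24 h. The immediate early genes had a median of -0.40 with all 23 lower (adjusted p = 5.71e-09, adjusted p = 0.0937 with an estimated correlation). The heat shock proteins had a median of -0.42 with 16 of 18 lower (adjusted p = 1.65e-06, adjusted p = 0.130 with an estimated correlation), and the NF-kB target genes -0.38 with all 7 tested of 24 lower (adjusted p = 0.000401, adjusted p = 0.256 with an estimated correlation). The activation markers had a median of -0.09 (adjusted p = 0.0177, adjusted p = 0.302 with an estimated correlation) and the cholesterol synthesis genes -0.12 (adjusted p = 0.0381, adjusted p = 0.262 with an estimated correlation). Adjusted over the list alone, 2 immediate early (4 with the donor block), 8 heat shock, 1 NF-kB, 2 activation and 2 cholesterol genes passed, all lower, while over all genes CD69 was the 1 member called. The activation call ended without no IgG1 4 h replicate 1 (adjusted p = 0.0665) or no IgG1 24 h replicate 1 (0.0827), and the cholesterol call without no IgG1 4 h replicate 1 (0.201) or no IgG1 24 h replicate 2 (0.114). The count of 9 genes was 2 without either no IgG1 24 h array and 3 without no IgG1 4 h replicate 2.

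With IgG1, 42 genes changed between 4 h and 24 h, 11 higher and 31 lower at 24 h, each the same way in both donors. All 9 genes that fell without IgG1 were among the 31, where independent lists of these sizes would share 0.0345 genes. These comparisons share no array, but they share the donors and 1 estimate of each gene's spread. They are therefore not independent, and 0.0345 is not the overlap to be had by chance. IFIT3 stood at -3.37 ± 0.32, IFIT2 at -3.01 ± 0.14, IFIT1 at -2.96 ± 0.22 and ISG20 at -2.24 ± 0.13 (adjusted p = 0.00187). With a gene's probes averaged IFIT3 stood at -1.68 and IFIT1 at -1.59, both called. Effector genes fell as well, with CCL4L1 at -2.46 ± 0.30 (adjusted p = 0.018), CCL3 at -2.02 ± 0.30, GZMH at -2.19 ± 0.20, GZMB at -1.89 ± 0.18, GZMA at -1.80 ± 0.22 and FASLG at -1.56 ± 0.18. IFNG stood at -3.18 ± 0.56, with an adjusted p of 0.0677 without and 0.0144 with the donor block, CCL4 at -1.38 ± 0.33, with 0.179 and 0.0144, and CCL3L1 at -2.59 ± 0.51, with 0.105 and 0.0324. The receptor genes CD160 and VSIR stood at -2.07 ± 0.24 and -1.68 ± 0.16. The genes that rose most were CD52, a surface glycoprotein of lymphocytes, at 1.98 ± 0.20 (adjusted p = 0.00997), SLC75A1 at 1.86 ± 0.17, EBI3 at 1.46 ± 0.12, the integrin gene ITGB7 at 1.33 ± 0.18 and ESPL1 at 1.28 ± 0.13. CCL4L1 (-1.94, adjusted p = 0.0653) and CCL3 (adjusted p = 0.0517) were not called when a gene's probes were averaged. The falls of effector genes with IgG1 include any change with time in culture. Without IgG1, CCL4L1 also went from log2 levels of 9.58 and 10.52 in the donors at 4 h to 8.99 and 9.39 at 24 h. GZMA did not fall there, with 10.32 and 10.20 at 4 h and 11.04 and 10.35 at 24 h.

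With IgG1, 7 lists fell between 4 h and 24 h. All 23 interferon-stimulated genes were lower, with a median of -1.20 (adjusted p = 3.09e-31, adjusted p = 0.0544 with an estimated correlation), and 11 were called over all genes against 17 adjusted over the list alone. The cytotoxic list had a median of -0.36 with 4 members called (adjusted p = 2.40e-08, adjusted p = 0.0544 with an estimated correlation). The cytokine list had a median of -0.40 with 2 called, and 6 with the donor block (adjusted p = 8.19e-06, adjusted p = 0.0600 with an estimated correlation). The immediate early list had a median of -0.37 with 1 called, and 3 with the block (adjusted p = 5.53e-07, adjusted p = 0.0544 with an estimated correlation), and the activating receptor list -0.35 with 1 called (adjusted p = 3.48e-05, adjusted p = 0.0544 with an estimated correlation). The heat shock list had a median of -0.27 with 0 called in limma, and 2 with the block (adjusted p = 3.48e-05, adjusted p = 0.106 with an estimated correlation). The inhibitory receptor list, with a median of -0.03, a mean of -0.42 and 6 of 12 members lower, had 3 members called (adjusted p = 0.0154, adjusted p = 0.126 with an estimated correlation), and its call ended without IgG1 24 h replicate 1 (adjusted p = 0.0642). Adjusted over the list alone, 5 cytotoxic genes, 9 immediate early genes, 5 members of the activating receptor list and 5 heat shock genes passed, all lower, with 8 cytokine genes and 4 inhibitory receptors lower and 1 of each higher. With the block 1 heat shock gene passed higher too.

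The count of 42 became 82 with the donor block (22 higher and 60 lower, all 42 among them), 69 with the stricter filter and 73 with a trended and robust variance. It was 25 without IgG1 4 h replicate 1, 5 without IgG1 4 h replicate 2, 15 without IgG1 24 h replicate 1 and 8 without IgG1 24 h replicate 2.

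Markers of other blood cells were read as a check on changes in cell composition between groups. Other cells present equally in all groups would not show in these comparisons, so purity itself was not tested. The lists had 4 to 11 tested members each. None of the 7 marker lists (monocytes, B cells, T cells, platelets, erythroid cells, dendritic cells, neutrophils) was called in any of the 5 comparisons with limma's camera, with or without the donor block, and no member was called. The medians lay between -0.06 and 0.10 for IgG1 at 4 h and between 0.01 and 0.16 for IgG1 at 24 h. The T cell gene CD3E stood at -0.18 ± 0.10 at 24 h (-0.12 without no IgG1 24 h replicate 1). The erythroid list had the smallest adjusted p of the 7 at 24 h, 0.252 without and 0.0509 with the donor block, and 0 and 2 members passed adjusted over the list alone. In it the hemoglobin gene HBA2 stood at 1.98 ± 0.72 (adjusted p = 0.427), HBA1 at 0.39 ± 0.21 and HBB at 0.13 ± 0.37, where HBA1 and HBA2 are near-identical copies whose separate values are uncertain. Without no IgG1 24 h replicate 1 or 2 HBA2 stood at 0.78 and 3.17, HBA1 at 0.13 and 0.64, and HBB at -0.30 and 0.56, and without IgG1 24 h replicate 1 or 2 HBB stood at 0.43 and -0.17. The 10 program lists not yet named for the IgG1 comparisons (NF-kB targets, NK lineage transcription factors, interferon-gamma and antigen presentation, glycolysis, oxidative phosphorylation, cholesterol synthesis, cell cycle, ribosome biogenesis, the integrated stress response and heat shock proteins) were not called at 4 h or 24 h, with adjusted p between 0.0551 and 0.880.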

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

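The tests of equally bright genes, of cell composition and of CD56bright genes below were chosen only after the fall of the cytotoxic genes had been seen, and the composition test and the readings of the tests of the brightest genes, of 1 array left out at 4 h and of shared effects were changed after their own results were seen.

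The test of the difference between times picked out 5 lists whose IgG1 effect differed between 24 h and 4 h in limma's camera. The effect was lower at 24 h for cytokine genes (median difference -0.31, adjusted p = 0.00353), cytotoxic genes (-0.52, adjusted p = 0.000228), the activating receptor list (-0.20, adjusted p = 0.0323) and interferon-stimulated genes (-0.37, adjusted p = 0.00098). It was higher for oxidative phosphorylation genes (0.23, adjusted p = 0.0402), all 11 tested of which were lower with IgG1 at 4 h. With an estimated correlation 0 of the 5 were called. Probes with no gene name here were used in no comparison by gene, and 2 of them passed the threshold for IgG1 at 24 h and 7 for 24 h against 4 h with IgG1.

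The cytotoxic granule genes fell with IgG1 at 24 h, with GZMA at -2.38 ± 0.22 and GNLY, not called, at -0.18 ± 0.16. GNLY stood at -0.059 and -0.31 without no IgG1 24 h replicate 1 or 2, and at -0.057 and -0.31 without IgG1 24 h replicate 1 or 2. A general loss of bright transcripts is argued against. Set against the 100 genes closest to each in level without IgG1, all 13 tested cytotoxic members were lower, from -2.37 for GZMA to -0.01 for CTSW. The median difference was -0.37 (95% bootstrap interval over members -1.01 to -0.17, which treats the members as independent). A loss set by brightness alone would leave such differences around 0. The test planned for it, a median of -0.055 (-0.071 to -0.024) in the tenth of genes brightest without IgG1, above a bound of -0.21, decides less on a common distribution, where a planted loss of 2 came out there as -0.96 when put in the brightest 10% of probes but as 0 when put in the brightest 50%, with the cytotoxic median then at -0.52. Fewer NK cells among other blood cells could lower cytotoxic genes alike, yet their SD over 10 members was 0.728, above a simulated limit of 0.625, as in 2 earlier versions of this test (GZMA minus GNLY, -2.19 ± 0.27, with GNLY at -0.63 when its probes were averaged, and the SD over all 13 members, 0.691, limit 0.579). Of the markers, the monocyte, B, T, dendritic, neutrophil and platelet lists had medians of 0.01 to 0.08 (LYZ at 0.07 ± 0.14). The erythroid list went the other way (median 0.16, 5 of 6 higher, adjusted p = 0.252 with limma's camera and 0.0509 with the donor block, HBA2 at 1.98 ± 0.72). Most markers lie near the floor and the test was picked after its result. Fewer NK cells among other blood cells therefore stay open as an explanation, beside a response of each cell to IgG1. A loss of CD56dim cells, the mature NK cells rich in granzymes, stays open too. The 10 genes higher in CD56bright cells had a median of -0.10 (-0.41 to 0.42). GZMK, at -1.17 ± 0.56, is among those 10 and also in the cytotoxic list, so that test was not independent of the fall.

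No gene was called with IgG1 at 4 h in limma, where 967 had an unadjusted p under 0.05. Whether an IgG1 array that stands apart is the cause could not be decided: 0 genes were called without IgG1 4 h replicate 2, whose mean correlation with the others was lowest (0.938), but leaving out either IgG1 24 h array also took the 24 h count from 26 to 0. Smaller effects shared by the donors cannot be told apart from other causes: the covariance of the donors' effects over all genes was 0.0435 at 4 h and 0.0371 at 24 h, a difference of 0.00631 (95% bootstrap interval over genes 0.000967 to 0.0116), which goes against it. Large shared effects were fewer at 4 h, which goes with it. At least a 2-fold change in both donors was seen for 13 genes against 44 at 24 h (difference -31, 95% bootstrap interval over genes -46 to -18). By the mean of the donors the counts were 26 against 73. Both intervals treat genes as independent and hold the 2 donors fixed, so they do not measure the spread between donors or arrays. The bound set beforehand weighed all genes alike and could not decide the question.

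IHH, a developmental signalling gene, stood at 1.15 in both donors at 4 h and was among the highest statistics without passing the threshold (adjusted p = 0.206). An intensity-dependent shift of the IgG1 arrays might lift genes of unrelated tissues together, but 79 tissue-restricted genes fixed beforehand had a median of 0.0025 (95% bootstrap interval -0.020 to 0.031), and 0 of them rose by over 0.5. With all genes put into 10 groups by brightness, the medians at 4 h lay between -0.00035 and -0.0086 in the 6 dimmest and at -0.04, -0.06, -0.11 and -0.06 in the 4 brightest, a graded shift downward, against -0.02 to 0.01 over the 10 groups at 24 h. A small upward shift of the tissue-restricted genes cannot be told apart from none, since the interval ends just past the bound of 0.03. No biological explanation was tested.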

How the results depend on the processing

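All alternatives were chosen before the data were examined, and none was added after a result was seen. With the donor as a block, 53 genes were called for IgG1 at 24 h against 26, and 82 for 24 h against 4 h with IgG1 against 42; it also called cytokine (adjusted p = 0.0137) and glycolysis genes (0.0477) for 24 h against 4 h without IgG1 and the SOCS and STAT5 list with IgG1 (0.0309). Apart from these and the blocked values given with the results, the block changed no other list call, nor the call of another gene in a comparison it is named for. For IgG1 at 24 h, the mean of a gene's probes gave 12 genes, every probe tested 8, and the 4 arrays of 24 h alone 0 in limma. For 24 h against 4 h with IgG1, the 70th percentile filter gave 69 and eBayes with trend and robust 73. Quantile normalization, median centring and the donor as a random effect left these counts at 26 and 42. These alternatives could change little. The deposited arrays already shared a distribution, and the correlation within donors estimated for the random effect was 0.00435. With the correlation estimated from the data, 0 lists were called in each of the 5 comparisons; without the filter 5 lists were called at 4 h against 3.

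Leaving out 1 array gave 0 to 14 genes for IgG1 at 24 h, 2 to 8 for 24 h against 4 h without IgG1 (9 with all) and 5 to 42 with IgG1. It gave 2 to 6 lists at 4 h and 2 to 5 for the difference between times. The lone array of a group was then assumed to vary like the other groups. Values near 0 changed sign: IL2RA at 4 h ranged from -0.0017 to 0.84, CCL3 at 24 h from -0.032 to 0.28, CCL4 at 24 h from -0.032 to 0.48, HBB at 24 h from -0.30 to 0.56 and LYZ at 24 h from -0.026 to 0.17 (-0.072 with its probes averaged). Calls of single named genes were followed under only some alternatives with all arrays, among them the donor block and the mean of a gene's probes. Of 47 called results for named genes, 34 kept their call under all of those, and 4 under every left-out array. Other alternatives were not part of the 34. Testing every probe kept 7 of the genes called for IgG1 at 24 h, and a minimum absolute log2 fold change of 1 kept 19. Fewer arrays and more tests are part of the construction of some alternatives; otherwise the cause was not tested. The counts for IgG1 at 4 h and for the difference between times were 0 in limma under every alternative. An offset before the logarithm was not run, since the deposited values are on a log2 scale.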

Other observations

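The test of ATXN1 was chosen only after its values were seen.

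In the apoptosis list, 11 of 17 members had higher values with IgG1 at 24 h, with a median of 0.04. The list was not called without the donor block (adjusted p = 0.0798, adjusted p = 0.309 with an estimated correlation) and was with it (adjusted p = 0.044). Adjusted over the list alone, 5 members passed higher and 1 lower (0 lower with the block). BCL2L11, which encodes the death-promoting BIM, stood at 1.80 ± 0.40, the protective BCL2L1 and BCL2 at 1.32 ± 0.39 and 1.09 ± 0.31, and GADD45B at 1.27 ± 0.25, none past the threshold over all genes. Without no IgG1 24 h replicate 1 the values were 1.12 for BCL2L11, 0.81 for BCL2L1 and 0.69 for BCL2, which stood at 0.63 with its probes averaged. The SOCS feedback and STAT5 target list, with 4 members tested, passed with the block too (adjusted p = 0.0472, against 0.114 without it, adjusted p = 0.434 with an estimated correlation).

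Further genes with high values at 24 h, none called, belong to lists that were not called. CD83 stood at 1.95 ± 0.45 in the NF-kB list (adjusted p = 0.0551) and the chaperone HSP90AB1 at 0.97 ± 0.18 in the heat shock list (adjusted p = 0.0599). HLA-DMA, which helps load peptides onto MHC class II, stood at 1.37 ± 0.31 in a list with 13 of 19 members lower (adjusted p = 0.277). ASNS and CALR stood at 0.81 ± 0.15 and 0.77 ± 0.19 in the integrated stress list, with 7 of 13 higher (adjusted p = 0.606). Among the NK lineage transcription factors, BHLHE40 stood at 1.01 ± 0.27 at 24 h (list adjusted p = 0.795), and KLF2 and ETS1 at -0.95 ± 0.37 and -0.73 ± 0.19 at 4 h (list adjusted p = 0.530). Without no IgG1 24 h replicate 1 CD83 stood at 1.29, BHLHE40 at 0.66 and CALR at 0.50. At 4 h KLF2 stood at -0.35 and -1.54 without IgG1 4 h replicate 1 or 2, and ETS1 at -0.47 without IgG1 4 h replicate 1 and -0.46 with its probes averaged.

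ATXN1, which encodes ataxin-1, stood at -1.13 with IgG1 at 4 h (-1.03 and -1.22 in the donors) and at 1.14 at 24 h (1.18 and 1.10). The difference of 2.26 ± 0.39 did not pass the threshold in limma (adjusted p = 0.511) and was 1.24 with its probes averaged. Over the 8085 genes, the effects of the donors correlated with r = 0.489 (rho = 0.434) at 4 h and r = 0.367 (rho = 0.205) at 24 h, over genes, which are not independent replicates. At least a 2-fold change in both donors was seen for 9 genes higher and 4 lower at 4 h, and for 20 higher and 24 lower at 24 h, with 0 genes that far apart in opposite directions at either time.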
